A study of Mus musculus with 8 samples.

How the data were processed

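Messenger RNA was measured by RNA sequencing in naive CD8 T cells taken from the spleens of 3 month old C57BL/6 mice, with 4 Brca1 wild type (WT) libraries and 4 Brca1 heterozygous (Het) libraries. Per the labels' protocols, the cells were isolated directly from splenocytes, RNA was extracted on silica columns, and stranded libraries were made from polyadenylated RNA. Libraries are named here by genotype and by the number in their sample title: WT 45, 54, 57 and 65, and Het 31, 53, 56 and 139. The 2 genotypes share no number, and the labels give no sex, litter, isolation day or sequencing batch. The labels do not say in so many words that each library came from a separate mouse, so p-values measure the spread between these libraries.

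The authors deposited 1 table of normalized read counts, a signal per gene on a linear scale with 1 decimal, for 22609 genes and the 8 libraries. CASAVA, TopHat2, HTSeq, DESeq and the mouse build mm9 are named, without versions or roles, per the submitters' processing notes. The normalization step and the strand setting of the counting are not given in the sources used here. The deposited signal values were checked, and the sorted values of the 8 libraries were the same up to ties: of the 9513 ranks with a mean of at least 100, 100% lay within 2% of their mean over the 8 libraries. The libraries had therefore been brought to 1 shared distribution (quantile normalization), which sets every total to about the same sum and hides any difference in total RNA. Differences in depth remain visible only in the number of genes at 0 and the spacing of low values. The total was between 27488636.8 and 27489670 in the 8 libraries, and says nothing about how many reads each had. Whole reads could not be recovered over the range of values, so no count model was used.

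The lowest value above 0 in a library is the value given to a gene with 1 read, and it was 0.2 to 0.3 in WT and 0.9 to 1.9 in Het libraries. The number of different values up to 100 estimates the reads behind a value of 100, since each whole read number takes 1 value. It was 106, 125, 112 and 128 in WT 45, 54, 57 and 65, and 121, 106, 74 and 85 in Het 31, 53, 56 and 139. At a value of 100 the precision was thus that of roughly 100 reads in every library, and differences of 1 or 2 units near 0 are about 1 or 2 reads in Het and several reads in WT libraries. PCR copies were not marked, so reads are not independent molecules.

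Genes with a mean of at least 10 over the 8 libraries were tested, which left 12048 genes. The test was limma 3.58.1 in R 4.3.3, with a trend on mean level, on log2(value + 1), 2-sided, with Benjamini-Hochberg adjustment over the 12048 genes and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Differences of single values between the genotypes were tested with an exact 2-sided permutation test over all 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move on balance 1 way. The p-values were adjusted over the 33 lists with at least 3 tested members. Tissue lists added after the values had been seen were adjusted separately, over those added lists alone. The mean log2 level of a list is taken over all its members found, tested or not.

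The test, the filter, 34 gene lists with 682 genes and the alternatives were chosen before the data were examined, and 668 of the list genes were found in the table. The lists covered DNA repair, the p53 response, T cell states, metabolism, and markers of other cells that an isolation from spleen could hold. The genes named in the text were Brca1, the 10 genes with the largest decrease among those past the threshold with a mean of at least 50 in 1 genotype and no overlap of the genotypes, up to 5 genes nearest the threshold in a direction without calls, and up to 3 members with the smallest unadjusted p of each list, or 4 where more passed. Not all genes that the rule takes are described in the text, and a few of them are not reported here and were not screened for libraries far from the others. Unnamed gene models and antigen receptor segments were left out. The genes nearest the threshold also had to have a mean of at least 50 in 1 genotype and no overlap of the genotypes. Rell1, Rhoh, Phactr2, H2-Q6, H2-K2, the other members of the added lists and a few marker genes named for their level were chosen after their values had been seen, as were 7 tissue lists (neuron, Schwann cell and nerve, glia, epidermis, fibroblast and matrix, skeletal muscle, liver).

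Alternatives were the pseudocount (0.5 or 5), the filter (any value above 0, or a mean of at least 50), TMM factors, equal totals, quantile normalization of the log2 values, array weights, no trend, a robust fit, B cell markers or Y-linked genes as a covariate, and leaving out each library in turn. Count models on recovered reads had been planned on the condition that reads could be recovered, and were not run. Alternatives added after seeing the data were a mean of at least 200, leaving out WT 45 and 54 or Het 31 and 139, the neuron list or the heat shock list as a covariate, and removal of linear trends on transcript length and GC content from each library. Transcript length and GC content came from the GENCODE annotation, and the order of genes from a RefSeq annotation, of the GRCm38 assembly. That assembly is not the build of the deposited table, so no coordinates are given. Of the 12048 tested genes, 11919 (98.9%) had a length.

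The scripts were tested on simulated data with the real genes and spreads for the comparison of Het with WT. Of 100 genes changed by 1 on the log2 scale 71 were called, of 100 changed by 3 on that scale 95 were called, and 12 of 11848 unchanged genes were called. With no changed gene, 2 of 12048 were called. Of 10 random lists shifted by 0.5 on the log2 scale 10 were called, and of 20 unshifted lists 0. The simulated genes varied independently of each other, without structure between libraries. In the 9 real lists that passed, the estimated correlation between genes was 0.242 to 0.881. The simulation therefore checks the scripts and does not show how many real calls are false.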

Results

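RNA sequencing was carried out on naive CD8 T cells, the antigen-inexperienced precursors of cytotoxic T cells, from the spleens of 3 month old WT and Brca1 Het mice, with 4 libraries of each genotype. Brca1 acts in homologous recombination, the repair of DNA double strand breaks from an intact copy. The comparison asked which transcripts of these cells differ when 1 Brca1 copy is affected. How the allele was made is not given in the labels. The T cell genes were at high levels in all 8 libraries: Cd8a, a chain of the CD8 coreceptor, had normalized read counts between 40591 and 50265.2.

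The deposited values had the same distribution in each library, with a total near 27489670, so depth was compared through the number of genes above 0 and the spacing of low values. A value of 100 stood for an estimated 118 ± 10.5 reads in WT and 96.5 ± 21.1 in Het libraries (SD, n = 4 each, exact permutation p = 0.143). Genes above 0 numbered 15490 ± 96.1 in WT and 14270 ± 391 in Het libraries (SD, n = 4 each, exact permutation p = 0.0286, the smallest the test can give). Spearman correlations across the tested genes, which are not independent replicates, were 0.983 to 0.992 within WT, 0.976 to 0.985 within Het and 0.969 to 0.989 between the genotypes.

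Brca1 itself was at a low level and did not pass the test. Its normalized read count was 208.1, 148.6, 168.3 and 206.2 in WT 45, 54, 57 and 65, and 174.5, 142.2, 126.7 and 169.6 in Het 31, 53, 56 and 139. The means were 183 ± 29.3 in WT and 153 ± 22.7 in Het (SD, n = 4 each), a log2 difference of -0.25 (SE 0.20, 95% interval -0.69 to 0.18, limma adjusted p = 0.742, exact permutation p = 0.171). The interval leaves out a difference of -1, that is, of 2-fold. Whether reads of the affected allele are still counted on the gene cannot be read from a value per gene, so Brca1 gave no check of the genotype labels.

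The genes with the largest decrease in Het libraries included genes known from nerve, glia and connective tissue. Mtap1b, a neuronal microtubule protein, fell from 1379 ± 663 in WT to 23.6 ± 35.1 in Het, by 6.63 on the log2 scale (SE 0.84, limma adjusted p = 0.0102). Prune2, abundant in nervous tissue, fell from 638 ± 308 to 7.25 ± 3.00, by 6.18 (SE 0.48, limma adjusted p = 0.000933). Apod, a lipid carrier of Schwann cells and fibroblasts, fell from 554 ± 264 to 14.8 ± 18.01, and S100b, a calcium-binding protein of glia, from 191 ± 66.6 to 5.25 ± 6.57 (limma adjusted p = 0.0142 and 0.00667). Kcna1, a potassium channel of axons, Pclo and Snap25, which act at synapses, Ptgds, a prostaglandin synthase of brain, and the imprinted genes Meg3 and Peg3 completed the 10 largest decreases among changed genes with a mean of at least 50 in 1 genotype. Their log2 changes lay between -6.08 and -5.10, with limma adjusted p from 0.00292 to 0.0254. Kcna1 and Pclo were listed at 0 in 3 of the 4 Het libraries.

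Altogether 62 of 12048 tested genes changed by limma, all of them lower in Het, and 60 of the 62 changed at least 2-fold. Of the 62, 50 had a Het mean under 20 and only 2 a Het mean of at least 100. The median of the changed genes' means was 89.9 in WT and 4.41 in Het. At an unadjusted p under 0.05 there were 987 genes, 457 higher and 530 lower in Het, and the genotypes did not overlap in 602 genes (4.997%, where chance gives 2.86%). Without WT 54, 57 or 65 the test called 16, 11 and 16 genes (13, 10 and 15 of the 62), without Het 31, 53 or 139 it called 27, 21 and 30 (26, 21 and 30 of the 62), and without WT 45 or Het 56 it called 57 and 91 (40 and 56 of the 62). Of these, 3 genes without Het 56 and 1 without WT 65 were higher in Het.

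Genes of other tissues differed with genotype as groups. Members of a neuron list were lower in Het in 23 of 23 tested genes, with a median log2 change of -3.83 (14.3-fold), and members of a Schwann cell and nerve list in 15 of 16 (median -3.30). A glia list was lower in 7 of 8 genes (median -3.18) and a fibroblast and matrix list in 21 of 21 (median -2.49). These lists fell with an estimated correlation as well (camera adjusted p = 0.0115, 0.0115, 0.0115 and 0.0270, adjusted over the added tissue lists alone). They were written after the changed genes had been seen and hold 16 of the 62, so they are no independent evidence of the direction. Over its 29 members found, the neuron list had a mean log2 level of 5.17 ± 0.86 in WT and 1.92 ± 0.91 in Het (SD, n = 4 each, exact permutation p = 0.0286). Het 56 was at 3.24 and the other Het libraries at 1.20 to 1.75. An epidermis list was at 7.70 and 7.07 in WT 45 and 54, at 2.57 and 2 in WT 57 and 65, and at 2.30 to 4.77 in Het libraries (exact permutation p = 0.400). Its genes were lower in Het in 15 of 15 (median -1.59), a call that was lost with an estimated correlation (camera adjusted p = 0.431). Krt5, a keratin of basal skin cells, was at 1125.6 and 758.9 in WT 45 and 54 and at 51.8 or less in each of the other libraries. A skeletal muscle list did not pass (median -0.19, camera adjusted p = 0.964), and the genes of a liver list, such as Alb at 7.9 or less in every library, were too low to test. Members with a Het mean of at least 100 numbered 0 in the neuron and glia lists, 3 each in the Schwann cell and nerve and the epidermis lists, and 4 in the fibroblast and matrix list.

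**Figure D1:**
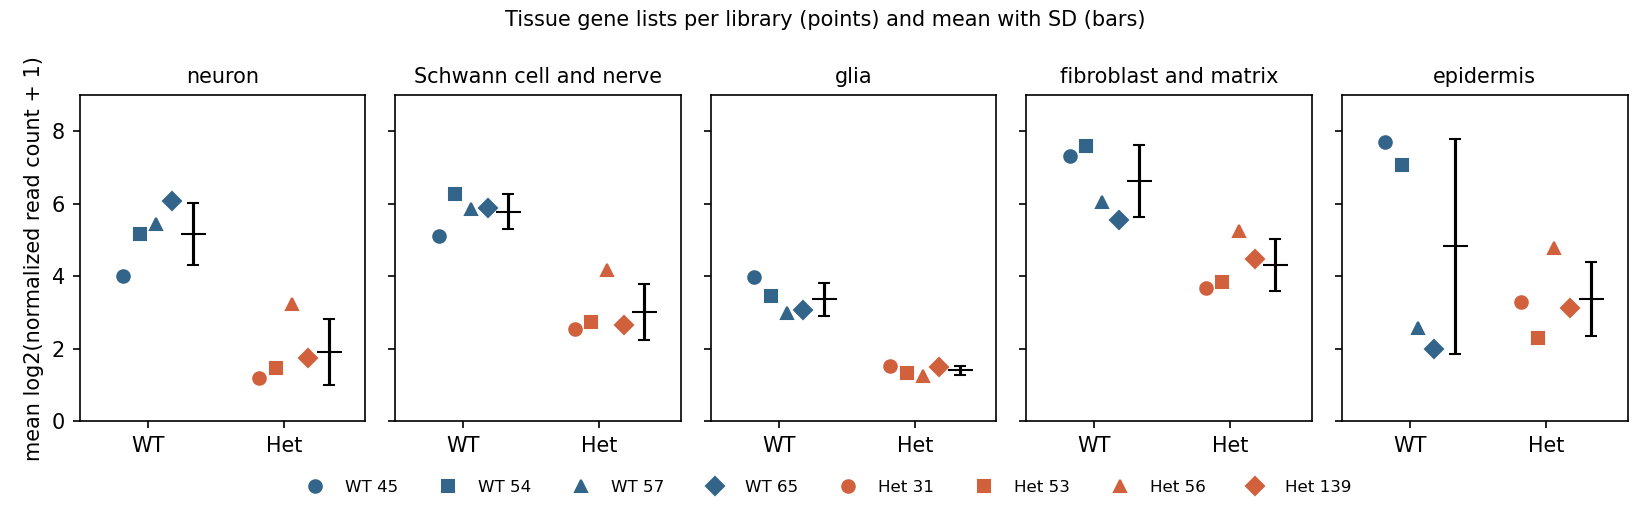
Mean log2(normalized read count + 1) over all members found of 5 tissue gene lists, 1 point per library and the mean with SD (n = 4) for each genotype. The neuron list lies at 4 to 6.07 in WT and 1.20 to 3.24 in Het libraries, and the epidermis list is high in WT 45 and 54 and lower in the other libraries.

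Rell1, Rhoh and Phactr2, with Het means well above the median of the changed genes, fell as well. Rell1, a member of the receptor expressed in lymphoid tissues family, fell from 1088 ± 29.6 in WT to 580 ± 84.8 in Het (SD, n = 4 each), by 0.92 on the log2 scale (SE 0.12, limma adjusted p = 0.0121). Rhoh, a GTPase of blood cells needed for T cell receptor signalling, fell from 5910 ± 532 to 3540 ± 595, by 0.75 (SE 0.12, limma adjusted p = 0.0254). Phactr2, a phosphatase and actin regulator, fell from 153 ± 13.5 to 69.2 ± 9.28, by 1.14 (SE 0.21, limma adjusted p = 0.0444). The genotypes did not overlap in any of the 3. H2-Q6, a nonclassical class I histocompatibility gene, was at 7787 ± 551 in WT and 5876 ± 378 in Het (log2 difference -0.41, limma adjusted p = 0.0885), and H2-K2 at 2758 ± 176 and 2021 ± 396 (-0.47, limma adjusted p = 0.252). Both have close paralogs, so their values are uncertain. Without WT 54 or WT 57 the limma adjusted p of Rell1 was 0.0595 and 0.0608, and Rhoh missed the threshold without WT 54, 57 or 65 or Het 53 or 139 (limma adjusted p between 0.0787 and 0.110). Phactr2 missed it without any 1 of the 8 libraries (limma adjusted p between 0.0561 and 0.152).

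No gene rose in Het by limma at the adjusted threshold. Nearest to it among the genes the naming rule allows was Dntt, the polymerase that adds nucleotides at antigen receptor junctions, at 503 ± 100.6 in WT and 846 ± 30.7 in Het (SD, n = 4 each, log2 difference 0.77, SE 0.15, limma adjusted p = 0.0636). Dntt was higher in each Het library (812.2 to 875.1) than in each WT library (366.2 to 608.6). Serpinb9, an inhibitor of granzyme B, was at 898 ± 47.2 and 1167 ± 60.5 (log2 difference 0.38, limma adjusted p = 0.163). Mrps33, of the mitochondrial ribosome, was at 62.8 ± 6.66 and 122 ± 25.2 (0.93, adjusted p = 0.171 by limma). Rcbtb2 was at 1180 ± 141 and 1600 ± 127 (0.44, adjusted p = 0.174 by limma). Gata1, a transcription factor of red cell and platelet precursors, was at 43.1 ± 11.96 and 91.0 ± 15.5 (1.09, adjusted p = 0.204 by limma). For Dntt and these 4 genes, no overlap of the genotypes was a condition of being named, so it adds no support.

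**Figure D2:**
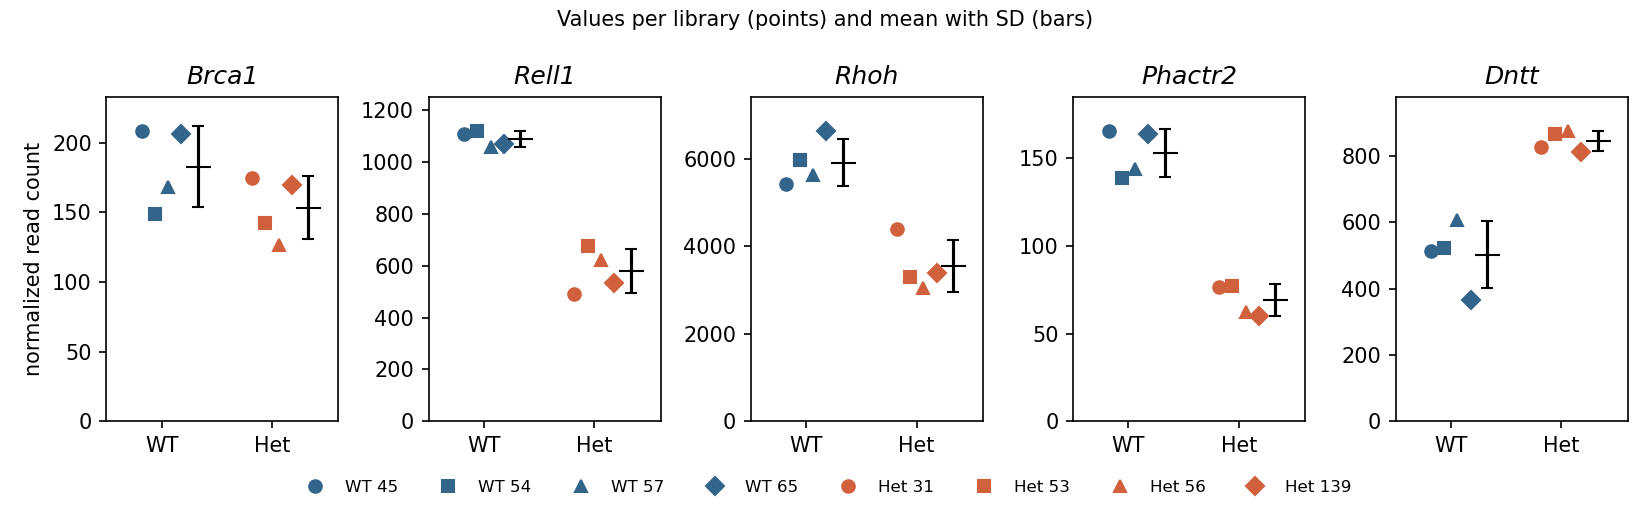
Normalized read counts of Brca1, Rell1, Rhoh, Phactr2 and Dntt, 1 point per library and the mean with SD (n = 4) for each genotype, each axis starting at 0. Rell1 lies at 1056.2 to 1117.7 in WT and 489.7 to 677.1 in Het libraries, whereas the Brca1 values of the genotypes overlap.

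The DNA repair lists, the pathways in which Brca1 acts, did not pass the test. In the homologous recombination list 15 of 26 tested genes were higher and 11 lower in Het (median log2 change 0.03, camera adjusted p = 0.518), and no member passed the limma test. Over all 28 members found, those below the filter included, the mean log2 level was 7.82 ± 0.06 in WT and 8 ± 0.13 in Het (SD, n = 4 each, exact permutation p = 0.0571). That difference of 0.19 compares with a mean log2 change of 0.113 over the 26 tested genes, so genes below the filter contributed to it. The members with the smallest p were Dna2, a nuclease, at 32.95 ± 17.3 in WT and 60.8 ± 10.6 in Het (log2 difference 0.97, limma adjusted p = 0.513), Fam175a, a scaffold of a Brca1 complex, at 499 ± 50.4 and 589 ± 55.4, and Palb2, which links Brca1 to Brca2, at 317 ± 48.2 and 255 ± 32.8. Nonhomologous end joining (20 genes, median 0.01, camera adjusted p = 0.898), the DNA damage checkpoint (20 genes, 0.03, 0.692), the Fanconi anaemia genes (17 genes, 0.06, 0.849) and R loop and RNA processing genes (24 genes, 0.01, 0.869) had no member past the threshold either. Fancd2, a core Fanconi protein, was at 25.8 ± 7.36 in WT and 44.1 ± 10.6 in Het (limma adjusted p = 0.625). The p53 target list was split into 13 higher and 13 lower genes (camera adjusted p = 0.855), with Sesn2 at 235 ± 33.6 and 167 ± 28.4 (limma adjusted p = 0.529). The neighbours of Brca1 on its chromosome did not pass (21 genes, median 0.03, camera adjusted p = 0.855).

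Genes of the naive T cell state and of T cell receptor signalling did not pass as groups. The naive T cell list had a median log2 change of -0.02 over 20 genes (camera adjusted p = 0.898), and no member passed the limma test. The receptor signalling list had a median of 0.03 over 26 genes (camera adjusted p = 0.862). Its member with the smallest p was Sla, an adaptor that lowers receptor signalling, at 5364 ± 199 in WT and 6408 ± 443 in Het (log2 difference 0.26, limma adjusted p = 0.372). Cell cycle genes (37 genes, median 0.06, camera adjusted p = 0.323), immediate early genes (27 genes, -0.10, 0.323), glycolysis genes (22 genes, 0.02, 0.855), apoptosis genes (22 genes, 0.03, 0.120), homing genes (22 genes, 0.12, 0.120), inhibitory receptors (18 genes, 0.10, 0.0658), heat shock genes (17 genes, -0.37, 0.120) and cytosolic DNA sensing genes (15 genes, 0.04, 0.484) did not pass. Among their members, Mki67, a proliferation marker, was at 400 ± 49.0 in WT and 299 ± 52.8 in Het (limma adjusted p = 0.535), Bmf, a promoter of apoptosis, at 190 ± 88.0 and 356 ± 42.8 (0.303), and Pdk1, a kinase that limits pyruvate oxidation, at 10000 ± 275 and 13510 ± 2037 (0.206). Gapdh, counted at only 68.4 ± 13.9 in WT and 36.0 ± 3.34 in Het, has many pseudogene copies and its value is uncertain.

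Interferon response, oxidative phosphorylation, cytotoxic, ribosomal and memory lists were higher in Het with the preset correlation, without a single member past the limma threshold. With an estimated correlation none of them passed (camera adjusted p = 0.722 for the first 4 and 0.743 for the memory list), nor did any with fry (lowest adjusted p = 0.482). Of the interferon response list, 33 of 35 genes were higher in Het (median log2 change 0.28, camera adjusted p = 1.16e-06), among them Trim30a at 4138 ± 399 in WT and 5053 ± 553 in Het and Oas1a, an antiviral enzyme, at 185 ± 70.6 and 357 ± 211. Of the oxidative phosphorylation list 36 of 42 were higher (median 0.17, camera adjusted p = 2.15e-05), with Uqcrc2 of complex III at 4964 ± 157 and 5724 ± 499. Of the cytotoxic list 16 of 19 were higher (median 0.48, camera adjusted p = 0.000158), with the protease Gzmb at 225 ± 78.9 and 432 ± 168. Of the ribosomal proteins 36 of 48 were higher (median 0.17, camera adjusted p = 0.00286), with Rpl7a at 1638 ± 323 and 2430 ± 804, and of the memory CD8 list 17 of 24 (median 0.15, camera adjusted p = 0.0275), with Il18rap, an interleukin 18 receptor chain, at 139 ± 51.5 and 273 ± 70.1. The interferon list was at a mean log2 level of 11.44 in Het 139, against 10.45 to 10.55 in the other Het and 10.13 to 10.78 in the WT libraries, and its median was 0.12 without Het 139 (camera adjusted p = 0.0268). Without Het 139 and 31 the oxidative phosphorylation, ribosomal and memory lists had medians of 0.00, -0.08 and -0.08.

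Markers of NK, B and myeloid cells were higher in Het with the preset correlation, without a member past the limma threshold. These calls were lost with an estimated correlation (camera adjusted p = 0.722, 0.753 and 0.753). NK cell markers were higher in 9 of 10 genes (median 1.08, camera adjusted p = 0.000788), with Klrb1c at 173 ± 107 in WT and 384 ± 239 in Het. B cell markers were higher in 17 of 18 (median 0.51, camera adjusted p = 0.0114) and myeloid markers in 16 of 17 (median 0.36, camera adjusted p = 0.0264), with Cd79b, a B cell receptor chain, at 1496 ± 531 and 2401 ± 1596 and the lysozyme gene Lyz2 at 751 ± 258 and 1374 ± 785. The B cell list was highest in Het 31, at a mean log2 level of 10.97, and lower in Het 56 (8.60) than in 3 of the 4 WT libraries. Stroma and endothelium markers were lower in 7 of 10 genes (median -1.31, camera adjusted p = 0.000817, and 0.722 with an estimated correlation), and Dcn, a collagen-binding proteoglycan, fell from 470 ± 166 to 24.8 ± 20.5 (log2 change -4.44, limma adjusted p = 0.00536). Dcn was the only changed gene in any list fixed before the data were examined. Adjusted over the list alone, 7 members passed, 5 of them in the stroma list and 1 each in the cytotoxic and memory lists. By fry's test of change in either direction the stroma list (adjusted p = 0.0315) and the platelet list (adjusted p = 0.00404) passed. Platelet markers were higher in 6 of 6 genes (median 0.57, camera adjusted p = 0.0504), with Gp1bb at 5.28 ± 0.89 and 16.0 ± 2.39. Markers of CD4 and regulatory T cells (9 genes, median 0.30, camera adjusted p = 0.120), plasma cells (4 genes, 0.42, 0.127), gamma delta and innate T cells (5 genes, 0.27, 0.363), plasmacytoid dendritic cells (7 genes, 0.28, 0.484), red cells (6 genes, 0.34, 0.484) and neutrophils (10 genes, 0.07, 0.862) did not pass.

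**Figure D3:**
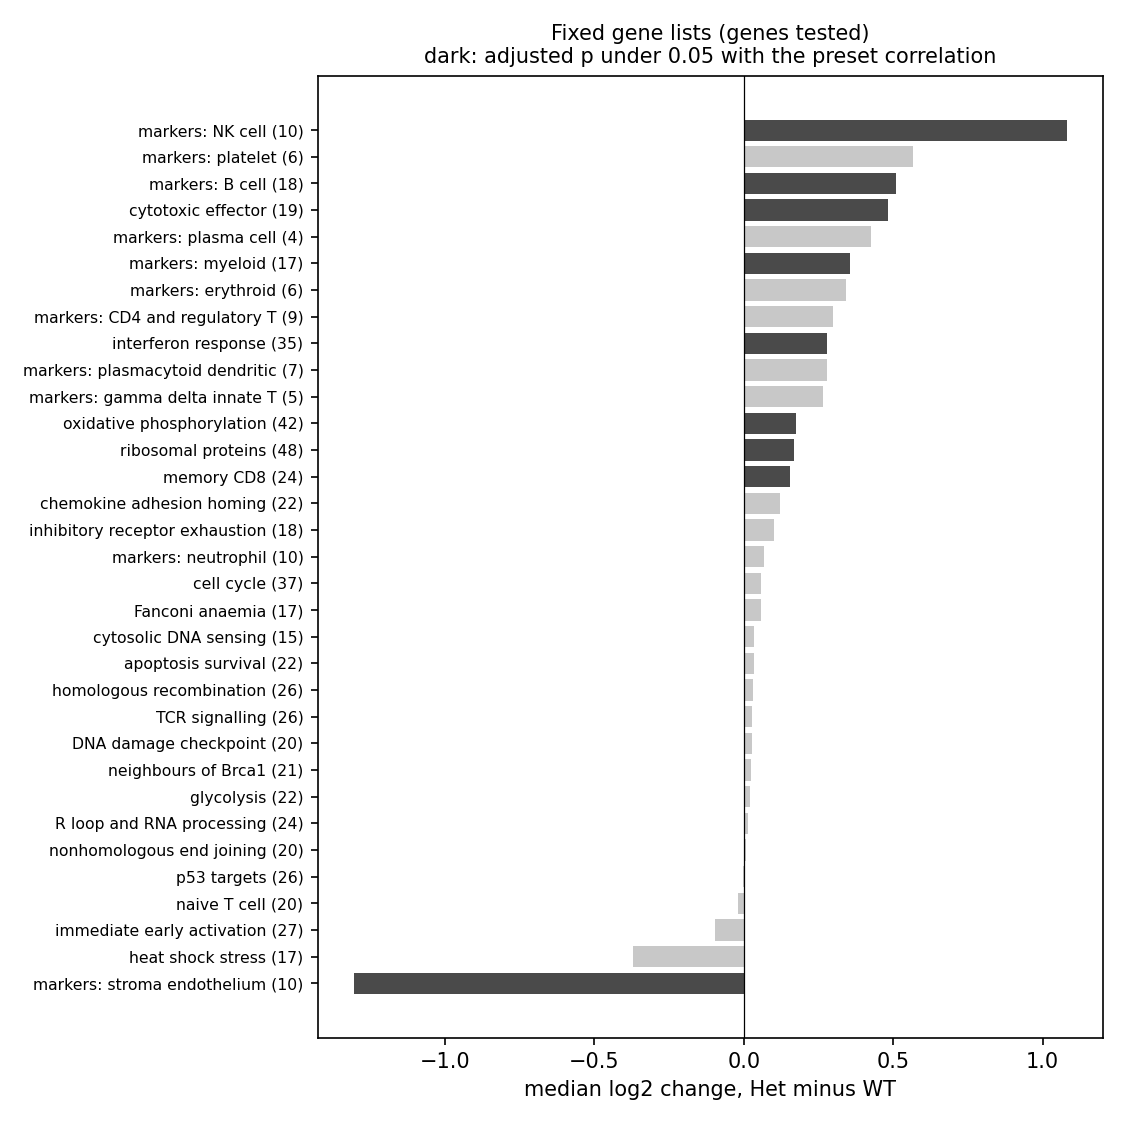
Median log2 change, Het minus WT, of the 33 gene lists fixed before the data were examined, with the number of tested genes in brackets and dark bars for an adjusted p under 0.05 with the preset correlation. The NK cell markers have the highest median (1.08) and the stroma and endothelium markers the lowest (-1.31), and the DNA repair lists lie within 0.06 of 0.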

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

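The tests of tissue RNA, of the value of 1 read, of depth on genes chosen in other libraries and of length trends list by list were chosen after the results had been seen. A library counted as far from the other 3 of its genotype when its gap to the nearest was nearly the whole range, which chance gives in about 1 of 20 groups, and 22 of 318 groups (6.92%) did. Of the 22, 8 were in Het 56, 5 in WT 54, 4 in WT 65, 2 in Het 53 and 1 each in WT 45, WT 57 and Het 139.

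Het 56 stood above the other Het libraries in 6 of the named genes and in the nerve list, though not in the glia list (1.26, others 1.32 to 1.52): Mtap1b at 76.1 (others 2.4 to 7.9), Kcna1 at 7.7 and Pclo at 1.9 (others listed at 0), Ptgds at 7.7 (others 1.0 to 1.9), S100b at 15.0 (others 0.9 to 3.2), Meg3 at 17.9 (others 1.0 to 3.8), and the Schwann cell and nerve list at a mean log2 level of 4.17 (others 2.54 to 2.73). In Het 56 a value of 1.9 is that of 1 read, so its Pclo rests on 1 read and its Kcna1 on few. Its Cd300a, a myeloid receptor, was lower, at 42.8 (others 97.1 to 105.8). In WT 45, Peg3 was at 359 (others 39.5 to 82.3). In WT 54, Slc4a1, a red cell anion exchanger, was at 466.8, Lyz2 at 1133.4, Siglech at 17.1, Fancd2 at 14.8 and Gapdh at 47.6. In WT 65, Cd40lg was at 157.9 (others 27.2 to 34.6), Itga2 at 53.4, Serpinb9 at 968.4 and the R loop and RNA processing list at 11.46 (others 11.49 each). In Het 53, Derl3, a plasma cell gene, was at 128.9 (others 57.8 to 60.2), and Igtp at 7371.8. The interferon response list was at 11.44 in Het 139 (others 10.45 to 10.55), and the neighbours of Brca1 were at 7.27 in WT 57 (others 7.10 to 7.11).

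The first pattern was the nerve, glia, matrix and skin transcripts of the WT libraries, where the 62 changed genes had a median log2 difference of -4.30 between the 2 deeper Het (31 and 53) and the 2 shallower WT libraries (45 and 57), with a sign fixed by the choice of genes on these libraries. With depth taken as the estimated reads at a value of 100 (121 and 106 in Het 31 and 53, 106 and 112 in WT 45 and 57), shallower Het libraries are argued against by 62 genes chosen only in the other 4 libraries, of which 57 were lower here in Het, with a median log2 difference of -3.69, although by genes above 0 (14656 and 14547, against 15550 and 15358) these Het libraries were still below these WT libraries. The value given to 1 read was at least 0.60 higher in each Het than in each WT library, so the normalization did not lower the lowest values in Het. That value depends on the number of genes above 0, which was itself lower in Het. It cannot decide how the normalization set higher values. RNA or reads of other tissues are a candidate explanation: the epidermis list minus the neuron list ranged over 7.77 on the log2 scale among the 4 WT libraries, Nefl of neurons was at 6.0 in WT 45 but 278.6 or more in WT 54, 57 and 65, and Krt5 of skin was at 9.6 and 0.2 in WT 57 and 65, although an isolation of CD8 T cells should remove such cells. The contribution of genotype stays open as untested, because libraries of both genotypes from 1 day or run are not identified.

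The second pattern was the lower Rell1 and Rhoh in Het. RNA of other tissues in WT that follows any 1 of the 5 tissue lists is argued against. The largest WT value was 1.06 times the smallest for Rell1 and 1.22 times for Rhoh. An excess following a list would have given at least 1.39 and 1.33, a narrow margin for Rhoh. Single changed genes can be steadier: Pclo was at 67.3 to 91.1 in WT, whereas each list ranged at least 1.99-fold. RNA of other tissues that does not follow the lists is therefore not excluded. Both genes lie on chromosome 5 of GRCm38 with 16 tested genes between them, and 0.283% of random gene pairs were as near. The pair was picked after its values had been seen, so that share does not give the chance of such nearness. A stretch of chromosome that differs between the mice may be shared. Of the 16 genes 1 had an unadjusted p under 0.05 (1-sided Fisher's exact p = 0.746), and the lowest log2 difference among them was -0.10, but 16 genes are too few to exclude a stretch with few affected genes. An effect of Brca1 dosage stays open as untested.

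The third pattern was the higher interferon, oxidative phosphorylation, cytotoxic, ribosomal and memory lists in Het. B cells in the libraries are argued against for most of it, since 4 of the 5 lists still passed with B cell markers as a covariate, at the preset correlation, though no list passed with an estimated correlation in this or any other setting. Trends on transcript length and GC content could account for the oxidative phosphorylation and ribosomal lists, neither of which passed without the trends (lower adjusted p = 0.42), and not for the interferon list, which still did at the preset correlation (adjusted p = 0.000427). Of the 5 lists, only 1 passed without the trends and only 1 without Het 139 and 31, the interferon list in each case. For the cytotoxic and memory lists neither can therefore be set apart from an effect of genotype. NK cells were not tested as a source, and their list shares Gzma with the cytotoxic and Eomes with the memory list. The mean log2 levels of the NK, cytotoxic and memory lists were all highest in Het 31 (7.54, 8.19 and 10.12) and lowest in WT 45 (4.79, 6.82 and 9.06). Chance was not excluded for the number of lists, since 11 of 35 splits reached 9 (highest other 13).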

How the results depend on the processing

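Against 62 changed genes in the main setting, TMM factors called 68 (all 62 among them), equal totals 62, quantile normalization 53 (52 of the 62), pseudocounts of 0.5 and 5 called 45 and 71 (45 and 60 of the 62), array weights 91 (61 of the 62, and 1 gene higher in Het), the robust fit 70, the fit without trend 85 (54 of the 62, and 10 genes higher in Het) and removal of length and GC trends 47. The data had already been quantile normalized, so equal totals moved little by construction. A second quantile normalization, of the log2 values, still changed the calls and kept 52 of the 62. Without the filter 123 genes were called (9 higher in Het), 121 of them at least 2-fold, and with a mean of at least 50 there were 14 and 13. With B cell markers as a covariate the counts were 39 and 37, and with Y-linked genes 9 and 9. Among the alternatives chosen after seeing the data, a mean of at least 200 gave 5 and 4, leaving out WT 45 and 54 gave 3 and 3, leaving out Het 139 and 31 gave 3 and 3, the neuron list as a covariate 0 and 0 (428 genes at an unadjusted p under 0.05 by limma), and the heat shock list as a covariate 25 and 23. The neuron list holds 4 of the 62 genes, and its levels do not overlap between WT (4 to 6.07) and Het (1.20 to 3.24). As a covariate it stands largely for genotype, so this loss of calls was largely fixed in advance. Leaving out 1 library gave 11 to 91 changed genes (3 higher in Het without Het 56 and 1 without WT 65) and 11 to 86 at least 2-fold changed ones. Of the 62 genes, a mean of at least 50 left 30 to be tested, of which 14 were still called. A mean of at least 200 left 8 to be tested, of which 5 were still called. With the neuron covariate the log2 difference of Apod shrank from -5.75 to -1.48 and that of Kcna1 from -6.08 to -1.88. Those of Dcn and Prune2 shrank from -4.44 to -2.98 and from -6.18 to -3.91, and none of these genes passed. For the other shifts the cause was not tested.

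The 9 lists that passed became 0 with an estimated correlation and 0 with fry, 2 without Het 139 and 31, and 4 each with the neuron covariate, the heat shock covariate and the length and GC trends removed, and 5 to 13 when 1 library was left out, the 5 without Het 31. List medians turned negative or to 0 without Het 139 and 31 for B cell (-0.01), myeloid (-0.04), memory (-0.08), oxidative phosphorylation (0.00) and ribosomal lists (-0.08). With the neuron covariate, which stands largely for genotype, the same lists had -0.37, -0.63, -0.06, -0.06 and -0.19, and plasma cell markers -1.21. Without length and GC trends oxidative phosphorylation had 0.00 and ribosomal proteins -0.03. The cause was tested only for the length trends. Brca1 stayed lower in Het without passing in the 25 alternatives that gave it a value. Its log2 difference was between -0.64, with the neuron covariate, and -0.10, and between -0.35 and -0.16 when 1 library was left out. A mean of at least 200 left Brca1 untested. Rell1 passed in 20 of 26 alternatives and Rhoh in 13 of 26. Genes and lists that passed in neither setting were not followed for sign, and 40 such gene values changed sign. The count models planned for recovered reads were not run. No paired analysis was possible because the genotypes share no replicate number. Values under about 20 rest on few reads and limit what can be said of the genes listed near 0 in Het.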

Other observations

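Cd4 was at 406.2 to 1078.3 over the 8 libraries, against at least 40591 for Cd8a. Genes of B and plasma cells reached higher values: Cd74, the class II invariant chain, was at 4016.8 to 25823.4 and Igj, the joining chain of immunoglobulins, at 1838.1 to 8712.2, both highest in Het 31. Cd44, which is high on memory T cells, was at 247.9 to 705.6. Xist, expressed from the inactive X chromosome of females, was at 12056.2 to 25721.8 in all 8 libraries. The Y-linked gene Ddx3y was at 15.7 in WT 45 and 49.7 in WT 54 and at 2.1 or less in each of the other libraries, and Uty was at 13.5 and 14.8 in those and at 1.9 or less elsewhere. These are the 2 libraries with the highest epidermis list. Scn10a, a sodium channel of sensory neurons, was at 131.6 in WT 65, at 15.0 in Het 56 and at 4.6 or less in the remaining libraries.

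Of the 35 ways to split the 8 libraries into 4 and 4, 2 called at least 62 genes, the real split included, so chance could not be excluded for that count. The highest other split called 353 genes, which points to a structure of the libraries other than genotype: it set WT 45, WT 65, Het 53 and Het 56 against WT 54, WT 57, Het 31 and Het 139. For the 60 genes changed at least 2-fold, 1 of 35 splits reached the count, the real split itself (highest other 28). That is the smallest share the 35 splits can give, so it argues against chance for this count without excluding it. A day or run that differed between the genotypes, which the labels do not give, could produce the same count. Chance could not be excluded for the 9 lists, which 11 of 35 splits reached (highest other 13).

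The libraries on the 2 sides of that split differed in heat shock genes, given here as values without a test because the sides were found from the data. Hsph1, a heat shock chaperone, was at 21019.9, 17300.9, 10522.7 and 14033.5 in WT 45, WT 65, Het 53 and Het 56, and at 8557.6, 8421.6, 2543.9 and 3553.2 in WT 54, WT 57, Het 31 and Het 139. The mean log2 level of the heat shock list was 10.25 to 10.76 in the first 4 and 9.68 to 10 in the other 4. Across genes, which are not independent replicates, the Spearman correlation of a library's deviation from the mean with transcript length was 0.304, 0.307, 0.186 and 0.114 in the first 4 and -0.109, 0.081, -0.331 and -0.405 in the other 4. Each side held 2 libraries of each genotype.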
